A study of Homo sapiens with 8 samples.

How the data were processed

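RNA of 8 prostate cancer cell lines was hybridised to two-colour cDNA arrays, 1 array per line, with the line in Cy5 and a common reference in Cy3, per the labels. The deposited values are signed log2 ratios, 1 per probe and array, with blanks where a spot had no value. The labels do not state scale, centring or direction. The log2 scale was read from the values, whose largest absolute value of 12.3 would exceed the range of a 16-bit scan as a natural or base-10 log. The array normalization used by the authors is not given in the sources used here, and the column medians lay near but not at 0. The direction, Cy5 over Cy3, was taken as likely from the dyes and stays unstated. No pair of arrays correlated below 0 over all probes (0.43 to 0.799). Scanner values were not used here, so neither signal over background nor spot quality could be examined.

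Gene names came from the platform annotation and were updated by Entrez ID through a RefSeq gene table, used for names and for the order of neighbouring genes. Of 43104 probes, 18312 had 1 gene symbol, 1033 had several and 23759 had none listed. The match covered 18293 of the probes with 1 symbol and changed 0 symbols. Probes with several symbols or none were named nowhere, and 20 probes of XIST or Y-linked genes were left out.

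Each array was centred on its median. Probes needed a value in at least 4 of 5 sensitive lines and 2 of 3 insensitive lines, which 14382 probes with 1 symbol met, and probes of 1 gene were averaged to give 9136 genes. Probes of 1 gene did not always move together: over 2690 genes with 2 or more probes measured in all 8 lines the median correlation of 2 probes was 0.669, and 0.936 for the 377 genes with an SD over lines above 1. Among genes past the threshold, the probes of CCNJL, OPN3, TM4SF1 and WDR82 differed in sign.

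The labels name only the lines. The lines of each class and the origins were set from textbook knowledge before the data were examined, as were the gene lists, the tests of classes, lists and origins, the rule for named genes and all alternatives but 1, in which PPC was an origin of its own. The names of the classes were changed afterwards, with the same lines in each. The counts of genes without overlap in other splits and in origin means, and the lowest p of the splits that keep lines of 1 origin together, were added after results were seen, as were some tests of the closing observations. The minimum of 5 measured members for a list test was chosen after the number of measured members was seen. Of 535 list entries 213 were named and measured. 1 further test is not reported here.

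Classes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with origin as a random block whose consensus correlation was 0.249, and Benjamini-Hochberg adjustment over all genes tested. Where leaving out a line, or taking PPC as an origin of its own, left a single same-origin pair, that correlation could not be estimated, and the value from all 8 lines was used. Lists were tested with cameraPR on the moderated statistics (preset correlation 0.01), with camera using an estimated correlation, with fry, and with a two-sided exact permutation of the list score over the 56 splits of 8 lines into 5 and 3. For 18 of the 22 lists these tests were made and adjusted together. Origins were compared by the moderated F test over genes measured in all 8 lines. Similarity, line-specific genes (2 log2 units beyond every other line) and differences within same-origin pairs were described without a test.

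Genes named were the 12 with the largest positive and the 12 with the largest negative difference among those past the threshold with classes that did not overlap, up to 4 members of each list with the smallest p, the 2 largest gaps above and below per line and same-origin pair, and the 3 largest differences in each direction within a pair. No tumour suppressor list member met the line-specific rule. SYP, DSP and CDH2 as line-specific genes were named after their values were seen.

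The class comparison was tested on simulated data of 9136 genes with 200 changed genes. It recovered 54.3% of genes changed by 2 log2 units, 93.4% of those changed by 4 and 98.2% of those changed by 6. Of its calls 4% were false. Each size had 5 simulations, with same-origin lines correlated at 0.25, close to the 0.249 fitted to the real data. These shares therefore hold for data built on the model's own assumption. In the real data the estimated correlation between list genes ran from -0.0996 (cancer testis) to 0.676 (cell cycle). The share of false calls there was not tested. Alternatives covered centring, quantile normalization, scaling, missing values, the probe rule, the origin block, the record block in the labels (PPC and MDA2B have later image record numbers), single probes, gap sizes and each line left out. Figures were drawn with matplotlib.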

Results

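Transcript levels were measured in 8 human prostate cancer cell lines, each on 1 two-colour cDNA array of 43104 probes. RNA of the line was labelled with Cy5 and a common reference RNA with Cy3. The lines were PPC, PC3, LAPC4, MDA2B, DU145, LNCaP, 22Rv1 and MDA2A, all established cultures of prostate carcinoma. LAPC4, MDA2B, LNCaP, 22Rv1 and MDA2A are called androgen-sensitive here, and PPC, PC3 and DU145 androgen-insensitive. How well these names suit each line, 22Rv1 among them, was not examined. MDA2A and MDA2B came from 1 patient. PPC was taken to be the line described elsewhere as derived from PC3, which the labels do not say, and on that reading there were 6 origins. The grouping of the lines and the origins are textbook knowledge and not part of the deposited labels. The lines of each class were chosen on a related textbook trait that is not reported here, and the names androgen-sensitive and androgen-insensitive were given to the same lines afterwards. The response to androgen was not measured, and the classes were not checked on the arrays.

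Between 28482 probes (MDA2B) and 32497 probes (LAPC4) carried a value. The median deposited value was -0.085 in PPC, 0.0315 in PC3, -0.014 in LAPC4, 0.08 in MDA2B, 0.009 in DU145, 0.157 in LNCaP, 0.096 in 22Rv1 and -0.071 in MDA2A. The MDA2B array had the widest values, with a median absolute deviation of 1.52 against 0.939 to 1.14 on the other arrays. The sign is given as line over reference, which is likely from the dyes in the labels, although the value table does not state it. If the ratio ran the other way, every sign would turn, and every higher and lower with it. The number of arrays limits the precision, and with 1 array per line the p-values measure the spread between lines of a class, not repeat error.

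The first comparison asked which genes differ between the androgen-sensitive and the androgen-insensitive lines. Androgen-sensitive lines had higher levels of TMPRSS2, EHF and FOXA1 and lower levels of ANXA1, MET and CAV1. TMPRSS2, a serine protease gene induced by androgen, had a mean log2 ratio of 5.11 ± 2.09 (SD, n = 5) in the sensitive lines and -1.92 ± 0.33 (SD, n = 3) in the insensitive lines. ANXA1, which encodes a phospholipid-binding protein, lay at -5.90 ± 0.77 (SD, n = 5) against 1.36 ± 1.39 (SD, n = 3). MET, the hepatocyte growth factor receptor, lay at -3.59 ± 1.35 (SD, n = 5) against 2.53 ± 0.72 (SD, n = 3).

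Of 9136 genes tested with limma, 132 passed a Benjamini-Hochberg adjusted p of 0.05, 52 of them higher and 80 lower in the sensitive lines. At an unadjusted p of 0.05, 1501 genes passed. The share that was higher was 39.4%, and 48.7% with values as deposited. All 132 had class values that did not overlap. Over all genes tested, 1340 (14.7%) did not overlap, where chance gives 3.57% if all 8 lines are independent, and the other splits that keep lines of 1 origin together gave 188 to 935. With origin means 2307 genes (25.3%) did not overlap, where chance gives 13.3% for 4 origins against 2. The smallest difference among the 132 was 1.53 log2 units, and the median over all genes tested was -0.05. With the mean of each origin as 1 sample, 62 genes passed, 49 of them among the 132. With the 6 arrays of the earlier image record numbers alone 48 passed, 31 of them among the 132. With the record block as a term 69 passed, and without the origin block 259. With PPC as an origin of its own 198 passed, an alternative added after the data were seen. Leaving out 1 line gave 77 genes without PPC, 85 without PC3, 75 without LNCaP and 68 without MDA2A.

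Among genes higher in the sensitive lines, TMPRSS2 differed by 6.86 log2 units (SE 1.03, limma adjusted p = 0.0159). EHF, an epithelial ETS factor, differed by 5.52 and FAM174B by 5.47. ARFGEF3 differed by 4.78 and KRTCAP3, a keratinocyte-associated gene, by 4.74 (SE 0.428, limma adjusted p = 0.00157). TMEM178B, CSMD1, PRR15L, TOX3, ELOVL7, FHDC1 and NUPR1 followed, with differences from 4.40 down to 3.99. ELOVL7 encodes a fatty acid elongase and NUPR1 a stress-induced nuclear protein. These fitted differences allow for lines of 1 origin, so they depart slightly from the plain difference of the class means.

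Among genes lower in the sensitive lines, ANXA1 differed by -7.32 log2 units (SE 0.667, limma adjusted p = 0.00157), MET by -6.03 and PDE1C by -5.47. PDE1C, a phosphodiesterase gene, lay at -4.44 in DU145 and at -0.62 and 1.46 in PPC and PC3. POPDC3 differed by -5.34 and CAV1, the main protein of caveolae, by -5.33 (SE 0.489, limma adjusted p = 0.00157). CLMP differed by -5.12, DCBLD2 by -4.88, GPAT3 by -4.80 and LPAR1, a receptor for lysophosphatidic acid, by -4.69. COPB2 (-4.39), the AP-1 subunit gene FOSL1 (-4.36) and FJX1 (-4.36) completed the 12. Among 49 genes past the threshold with more than 1 probe, all probes had 1 sign in 45. Genes were called on the mean of their probes, which favours 1 sign, and sizes could differ, as for ANXA2 (-5.19 and -0.21). The other genes past the threshold, TMPRSS2, ANXA1, MET and CAV1 among them, rested on a single probe that passed the filter.

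**Figure D1:**
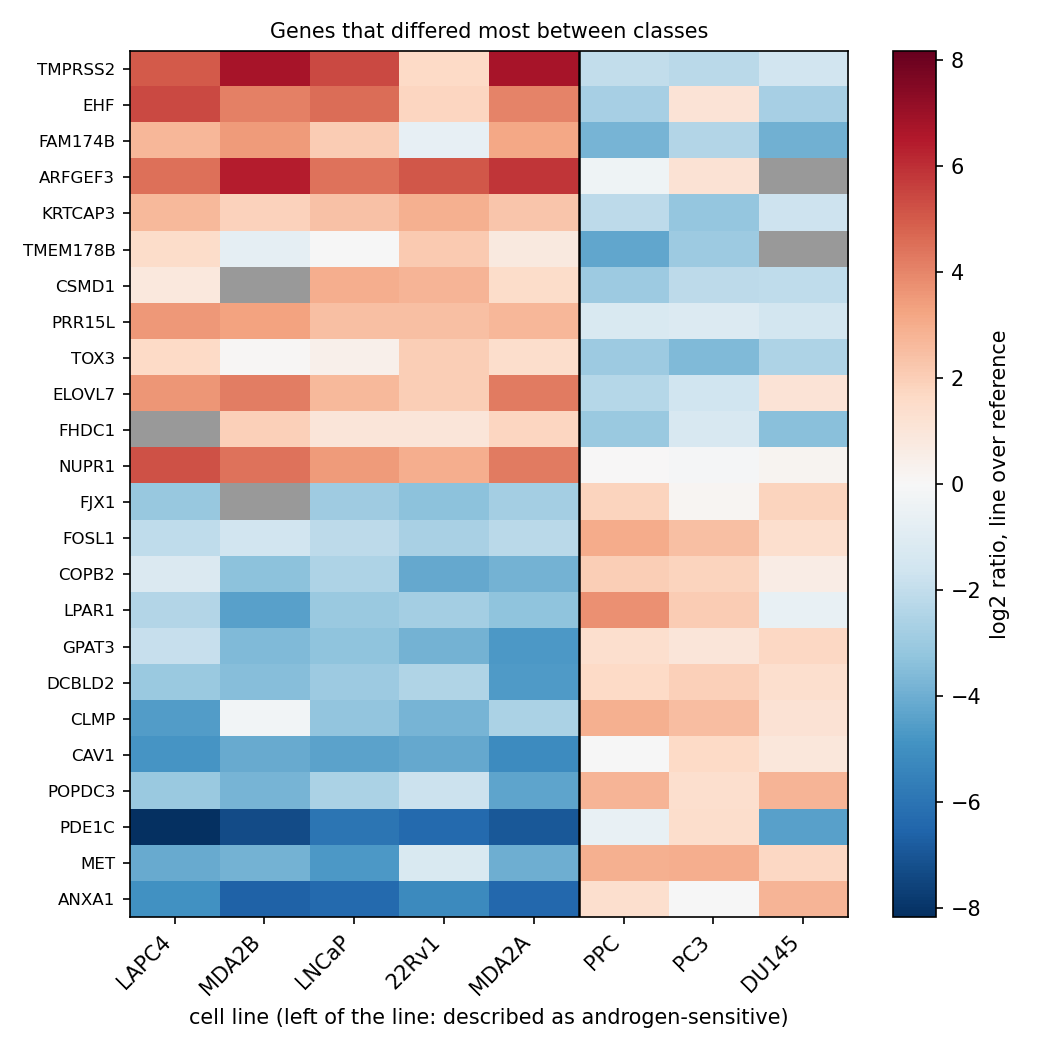
Log2 ratio (colour, line over reference) of the 24 genes with the largest differences between classes in each of the 8 lines. The 5 lines called androgen-sensitive are left of the black line, and grey marks no value. TMPRSS2 lies between 1.64 and 6.76 in the sensitive lines and between -2.19 and -1.55 in the insensitive lines.

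Androgen-responsive genes were higher in the sensitive lines as a list by the camera test with a preset correlation (adjusted p = 0.000132), and not past the threshold (adjusted p = 0.0836 with an estimated correlation). Of 15 measured members, 1 (TMPRSS2) rose and 14 did not pass, while 3 rose when adjusted over the list alone. The mean difference was 1.72 log2 units, and 14 of 15 members lay above 0. STEAP2, a metalloreductase gene, had a difference of 2.54, the prostate homeobox gene HOXB13 3.70 and PMEPA1 2.91, all short of the threshold over all genes. The insensitive lines were not alike: HOXB13 stood at 4.07 in PPC, 0.69 in PC3 and -2.08 in DU145. PMEPA1 stood at -2.37 in PPC and 1.74 in PC3. The exact permutation test of the list score gave p = 0.0179, the smallest that 56 splits can give (adjusted p = 0.0643).

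Luminal epithelial genes showed a mean difference of 2.03, with 14 of 14 measured members above 0. FOXA1, a pioneer factor of luminal cells, rose by 2.15 (SE 0.327, limma adjusted p = 0.0159), and 13 members did not pass. The count was also 1 when adjusted over the list alone. ELF3 (2.04), SPINT1 (2.98) and TSPAN1 (2.71) had positive differences. The preset-correlation camera test gave adjusted p = 1.126e-06, and adjusted p = 0.2805 with an estimated correlation. The list score was 0.29 in PC3, above 0.25 in 22Rv1 and 0.12 in LNCaP, and the exact permutation p was 0.0536.

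Mesenchymal genes were lower as a list by the camera test with a preset correlation (adjusted p = 3.446e-09), and not past the threshold (adjusted p = 0.0836 with an estimated correlation). Of 18 measured members 5 fell (ANXA1, CAV1, TGFBR2, MMP14 and CCN1) and 13 did not pass. When adjusted over the list alone 11 passed, 10 lower and 1 higher. TGFBR2, a transforming growth factor beta receptor, fell by 4.05 log2 units and the membrane-bound matrix metalloprotease gene MMP14 fell by 2.16. The mean difference was -1.57, with an exact permutation p of 0.0179. Basal epithelial genes had 5 measured members, of which LAMB3, a laminin-332 chain gene, fell by 4.25 and 4 did not pass. DST had a difference of -1.20, EGFR -0.96 and JAG1 0.88. Adjusted over the list alone 2 fell. The list's mean difference was -1.43 (camera adjusted p = 0.0462, and adjusted p = 0.2805 with an estimated correlation, exact permutation p = 0.0179). Its camera adjusted p was 0.0599 after quantile normalization and ranged from 0.000693 to 0.1368 over all settings.

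Cell cycle genes had no member past the threshold over all genes among 13 measured, and 2 fell when adjusted over the list alone. All 13 differences lay below 0, with a mean of -1.07 log2 units. The replication licensing gene MCM3 had a difference of -1.77, the mitotic kinase gene AURKA -1.95, UBE2C -1.45 and MCM6 -0.83. The camera adjusted p was 0.000132, and adjusted p = 0.3559 with an estimated correlation, and the exact permutation p was 0.0357. Scores were lowest in MDA2B (-1.32) and MDA2A (-0.93), and the MDA2B array had the widest spread of values.

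Cholesterol and fatty acid synthesis genes had 21 measured members, none past the threshold over all genes and 1 higher when adjusted over the list alone. ACACA, which makes malonyl-CoA, had a difference of 1.76, the desaturase gene SCD 1.25, SREBF2 1.21 and INSIG1 1.93. The mean was 0.43 (camera adjusted p = 0.0153, and adjusted p = 0.4449 with an estimated correlation, exact permutation p = 0.232). The camera call ended without PPC (mean 0.33, adjusted p = 0.0559) and without LAPC4 (0.26, adjusted p = 0.104). Cancer testis genes had 5 measured members, none past the threshold over all genes and 2 higher when adjusted over the list alone. MAGEA4 had a difference of 4.55, MAGEA6 5.47, SSX1 2.72 and PRAME 1.26. The insensitive lines were not alike: MAGEA6 stood at 0.85 in PPC and -6.08 in PC3, and MAGEA4 at -0.04 and -5.34. These 2 genes lie close together on the X chromosome and may not vary independently. The list's mean was 3.10 (camera adjusted p = 0.00644, and adjusted p = 0.1003 with an estimated correlation, exact permutation p = 0.0179).

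**Figure D2:**
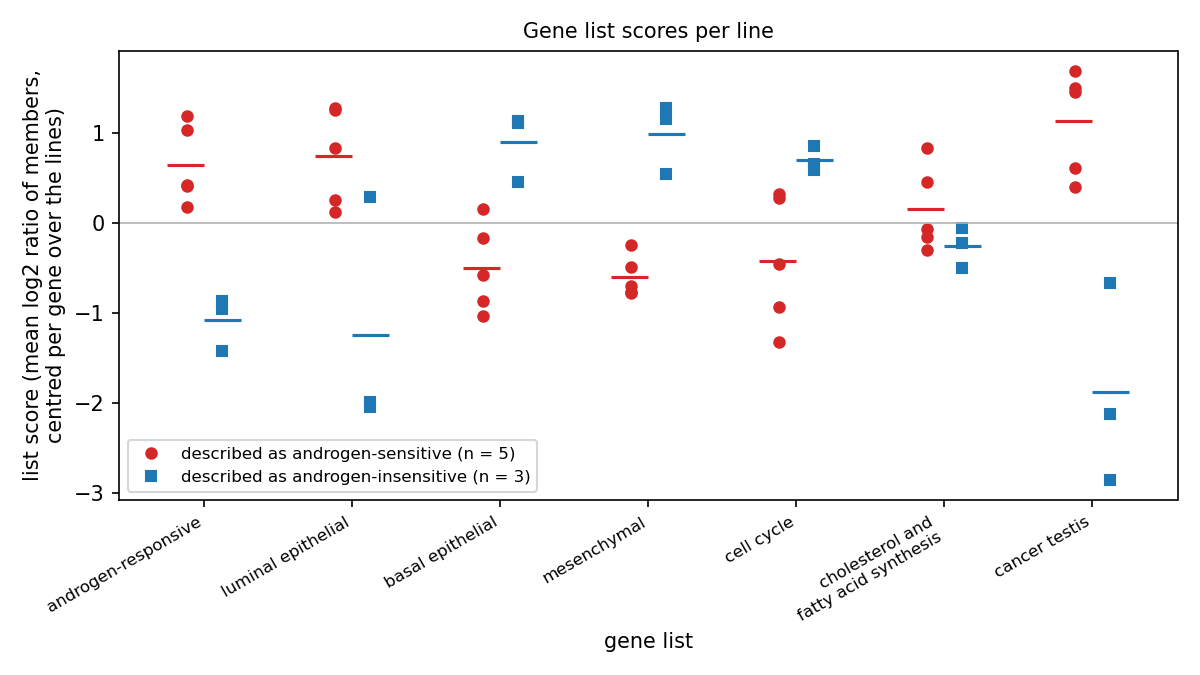
List score of 7 gene lists (mean log2 ratio of the members, centred per gene over the lines) in each line. Circles mark the 5 lines called androgen-sensitive, squares the 3 called androgen-insensitive and bars the class means. The androgen-responsive score lies between 0.18 and 1.19 in the sensitive lines and between -1.42 and -0.87 in the insensitive lines.

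The other lists did not pass the camera test. Among 13 ETS and MYC family genes EHF rose, ETS1 fell by 2.43 and 11 did not pass (camera adjusted p = 0.3182). Adjusted over the list alone 4 passed. ETV4 had a difference of -1.67 and ETV5 -2.51. Among 15 receptor tyrosine kinase and ligand genes MET fell, over all genes and when adjusted over the list alone, and 14 did not pass (camera adjusted p = 0.5112). The median of that list was 0.24 and its mean -0.44. EREG had a difference of -2.22, DDR1 0.95 and FGFR1 -1.37. Among 12 stromal and endothelial markers KDR, a receptor for vascular endothelial growth factor, fell by 1.92 and 11 did not pass, and 1 fell when adjusted over the list alone (camera adjusted p = 0.0848). LUM had a difference of 1.33, FAP -0.63 and COL1A1 -0.91.

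Among 12 nuclear receptors and cofactors none passed over all genes and 2 were higher when adjusted over the list alone, GATA2 (3.43) and NCOA1 (2.09), with RARB at 1.08 and ESR1 at -0.78 (camera adjusted p = 0.1204). Among 15 tumour suppressor and DNA repair genes none passed, over all genes or when adjusted over the list alone (camera adjusted p = 0.0967). CDKN1B had a difference of 1.53, CTNNB1 0.78, MAP2K4 0.67 and SMAD4 0.64. Of 6 oxidative stress and glutathione genes none passed over all genes and 2 were lower when adjusted over the list alone (camera adjusted p = 0.115). MGST1 stood at -1.24, TXNRD1 at -1.76, SRXN1 at -0.73 and GCLC at -0.40. Of 5 genes of the urokinase and matrix protease list none passed over all genes and 2 passed when adjusted over the list alone, TIMP2 at -3.19 and ADAMTS1 at 2.55, with ADAM9 at -0.41 and MMP13 at -0.15 (camera adjusted p = 0.669).

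No member passed by either count among 9 hypoxia and glycolysis genes (camera adjusted p = 0.558), 5 glucuronidation and steroid metabolism genes (camera adjusted p = 0.478) and 7 melanocyte markers (camera adjusted p = 0.887). ANKRD37 had a difference of 1.19, PGK1 -1.16, EGLN3 0.76 and PDK1 0.90. HSD17B4 had a difference of 0.68, UGDH 0.99, ALDH3A2 0.60 and CYP1B1 -0.45. MITF had a difference of -1.82, GPNMB 1.44, S100B -0.19 and PMEL 0.38. The melanocyte list had a median of 0.03 and a mean of -0.02, and its camera direction was up. Of 8 leukocyte markers none passed over all genes and 1 was lower when adjusted over the list alone (camera adjusted p = 0.122). LCP2 had a difference of -1.44, RAC2 -1.58, SRGN -3.60 and ARHGDIB -0.82, and the list score was 1.64 in PC3 and below 0 in the other 7 lines.

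Lists with fewer than 5 measured members had no list test, and none of their members passed over all genes. When adjusted over the list alone, 3 of 4 inflammatory cytokine and NF-kB genes and 1 of 4 interferon-induced genes were lower. TNFRSF12A had a difference of -2.96, CCL20 -1.58, IL7R -1.92 and IL6ST -0.33. IFIT2 had a difference of -2.11, IRF1 -0.62, BST2 -0.49 and ISG20 -0.06. None of 4 neuroendocrine genes (NCAM1 -1.25, SNAP25 -0.47, SYP 0.60 and NTS -0.05) and none of 3 liver markers (TF 1.39, FGB 0.07 and TTR 0.03) passed when adjusted over the list alone. No exact permutation p of any list passed after Benjamini-Hochberg adjustment, the smallest adjusted value being 0.0643. These tests count all 8 lines as independent, and the 12 splits that keep lines of 1 origin together could give no p below 0.0833. The fry test, which asks whether members move one way on balance, gave adjusted p = 0.0143 for the androgen-responsive list, 0.00314 for the mesenchymal, 0.0425 for the basal and 0.0143 for the cancer testis list. It gave 0.0602 for the luminal, 0.0932 for the cell cycle and 0.207 for the cholesterol and fatty acid list, and no other list passed.

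Uncentred log2 ratios of lines of 1 class correlated more highly than those of lines of different classes across 8101 genes measured in all 8 lines. MDA2B and MDA2A had the highest Pearson correlation of the 28 pairs, 0.818 (Spearman 0.772). PPC and PC3 reached 0.672 (Spearman 0.646), rank 7 of 28. Pairs of different origin correlated between 0.594 and 0.722 where both lines are androgen-sensitive, and at 0.564 and 0.572 where both are androgen-insensitive. The 15 pairs across classes lay between 0.384 and 0.502. With each gene centred over the 8 lines the same-origin pairs stood highest, at 0.426 for MDA2B and MDA2A and 0.399 for PPC and PC3, but the classes overlapped: MDA2B and 22Rv1 stood at -0.229, below DU145 and 22Rv1 at -0.189. The highest branches of the average-linkage tree held the 5 sensitive and the 3 insensitive lines. These correlations are across genes, which are not independent replicates.

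**Figure D3:**
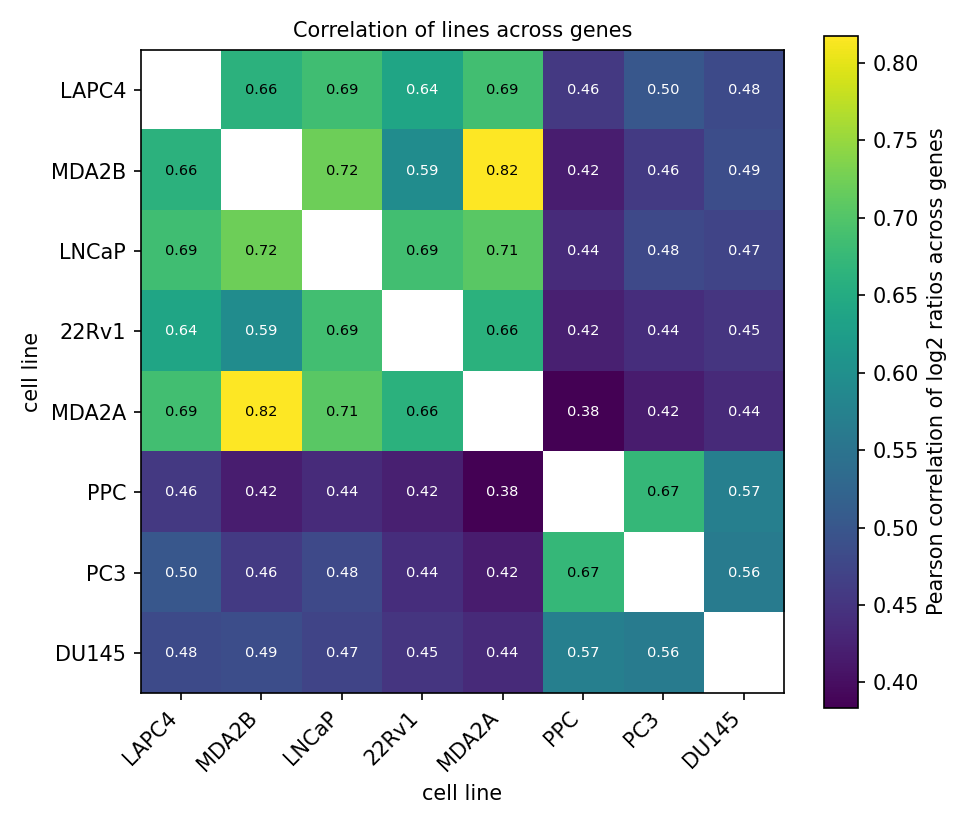
Pearson correlation of log2 ratios across 8101 genes for each pair of the 8 lines (colour and printed value). The 5 lines called androgen-sensitive come first. MDA2B and MDA2A reach 0.818, and pairs of different classes lie between 0.384 and 0.502.

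Across the 6 origins, 247 of 8101 genes differed by the limma moderated F test at a Benjamini-Hochberg adjusted p of 0.05, and 1559 at an unadjusted p of 0.05. The spread in this test came only from the differences within the 2 same-origin pairs. With arrays scaled to 1 spread, 18 genes passed.

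Single lines carried levels far from all others, given as values without a test because each line had 1 array. By the rule of 2 log2 units from every other line, DU145 had 28 genes above and 16 below, 22Rv1 had 27 above and 3 below, and PPC had 26 above and 31 below. LAPC4 had 14 above and 28 below, PC3 12 and 2, MDA2A 12 and 9, LNCaP 9 and 6, and MDA2B 4 and 12. The rule includes the line of the same origin, where there is one. Counts of PPC, PC3, MDA2A and MDA2B are therefore not comparable with those of the other lines. In DU145, CYP24A1, the vitamin D 24-hydroxylase gene, stood at 3.16 against at most -2.86 elsewhere, and CAVIN1, needed to form caveolae, at 1.35 against at most -4.01. TXNIP, a thioredoxin inhibitor gene, stood at -4.52 in DU145 and ST3GAL1 at -2.60. In 22Rv1, the small heat shock gene HSPB6 stood at 5.16 and PDK4, a pyruvate dehydrogenase kinase gene, at 4.44, with KRT10-AS1 at -2.34 and GALNT2 at -2.02. The synaptic vesicle gene SYP stood at 3.37 in 22Rv1 against at most -1.04 elsewhere.

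In LAPC4 the secretory gene CRISP3 stood at 4.80 and DIO2, a thyroid hormone deiodinase gene, at 3.36, with PHKA1 at -4.64 and CASP2, a caspase gene, at -3.80. In PPC the retinoic acid synthesis gene ALDH1A2 stood at 1.60 against at most -3.83 elsewhere and CNRIP1 at 3.56, with TCEAL8 at -6.15 and USP43 at -3.15. The desmosome gene DSP stood at -5.34 in PPC and the N-cadherin gene CDH2 at 0.12 against at most -2.14. In PC3, KLK6 stood at 2.06 and BST2 at -0.17, with ZNF302 at -1.98 and MAP1B at -3.49. In LNCaP, PRKD1 stood at 3.83 and PRKACB at 4.31, with MCUB at -2.99 and SPTBN1 at -4.71. In MDA2A, SLC4A4 stood at 4.64 and MAGEC1 at 2.76, with TTYH2 at -6.19 and CNRIP1 at -6.42. In MDA2B, WNT4 stood at 4.13 and GDF11 at 3.69, with ENTPD3-AS1 at -5.30 and CREM at -2.91.

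Lines of 1 origin shared some of these levels. PPC and PC3 together had 11 genes above and 13 below all other lines. PDE1C averaged 0.42 and SH3TC2 1.85 in the pair, the long noncoding RNA CRNDE averaged -4.67, and STAT3, a cytokine-activated transcription factor, averaged -5.34 against 0.10 to 1.68 elsewhere. MDA2B and MDA2A had 5 above and 5 below. The fibronectin gene FN1 averaged 2.31 against at most -2.10 elsewhere and SLC36A1 5.54, while NUDT16L2P averaged -3.83 and GIGYF1 -4.98.

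Lines of 1 origin also differed from each other, again without a test. Between PPC and PC3, 369 of 8868 genes lay at least 2 log2 units apart, 124 higher and 245 lower in PPC. MAGEA6 differed by 6.92, HS3ST3A1 by 5.97 and CD55, a complement regulator gene, by 5.57. LCP1, which encodes an actin-bundling protein, differed by -7.97, TSPYL5 by -7.59 and TCEAL8 by -6.78. Between MDA2B and MDA2A, 237 of 8535 genes lay that far apart, 81 higher and 156 lower in MDA2B. After quantile normalization 144 did, and the MDA2B array had the widest values (median absolute deviation 1.52). The collagen gene COL12A1 differed by 6.33, NUDT11 by 5.43 and BCL11B by 5.39. DKK1, a Wnt antagonist gene, differed by -7.53, the prostaglandin-degrading HPGD by -5.83 and PRKG1 by -5.36.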

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

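The test with 2 probes of 1 gene compared was chosen after results had been seen, and the fit with the mean of each origin as 1 sample, planned as an alternative, was taken as a test of shared origin only after its count was seen. A gap test among the 5 sensitive lines picked out 2 of 45 sets of values, and chance picks about 1 in 20. MET stood at -1.25 in 22Rv1, far above the next sensitive line at -3.88. The leukocyte list score stood at -0.0881 in LNCaP against -0.21 in the next line. In data outside the report's comparisons, 270 of 13934 probes without 1 gene symbol differed between the classes in a limma fit per probe. Of these, 104 were higher and 166 lower in the sensitive lines. The share was similar among probes with 1 symbol, of which 266 of 14382 differed in the same fit.

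The difference between the classes was weighed against grouping by chance, array batch and shared origin. Of the 56 splits of the lines into 5 and 3, only the real one (1 split) gave as many as 132 genes, and the highest other split gave 5, which excludes chance only if lines of 1 origin count as independent. Among the 12 splits that keep lines of 1 origin together, the real one (1 split) gave 132 and the highest other 4, and these are too few for a share under 0.05. With only the 6 arrays of the earlier record block 48 genes passed, and with 1 mean per origin 62 passed, both above the 5 that were set as the bound. Only 31 of the 48 and 49 of the 62 were among the original 132. A biological difference tied to androgen sensitivity may remain, but the classes come from outside the labels, and any other trait shared by the 3 insensitive lines stays open and untested.

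PPC and PC3 differed at 369 genes by at least 2 log2 units although PPC is described as derived from PC3. A shift of the later array batch would appear in MDA2B minus MDA2A as well, and the correlation across genes of that difference with PPC minus PC3 was -0.00159. The SD of PPC minus PC3 over genes was 1.56 times the SD between 2 probes of 1 gene (95% interval 1.5 to 1.63). It was 1.11 times when the plain difference of 2 probes is the yardstick. By the preset bound of 1.5, which the interval reached, the ratio decided nothing about array noise. The differences of 2 probes of 1 gene correlated at 0.591 across 3341 genes (95% interval 0.554 to 0.626). Spot noise that is independent between probes does not by itself give such a correlation. However, this correlation is the SD ratio in another form, with a bound set after results had been seen. It is therefore no separate test, and noise shared by the probes of a gene stays open. Divergence in culture, or RNA harvested under different conditions, could account for the rest, and neither was tested.

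Probes with a value on 1 side only were 60 in number, 40 measured in all 5 sensitive lines alone and 20 in all 3 insensitive lines alone. Of the 56 splits 21 gave as many, up to 121, so grouping by chance is not excluded for these probes.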

How the results depend on the processing

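All alternatives were chosen before the data were examined, except PPC as an origin of its own. The cause of each change below was not tested. The class difference held between 114 and 150 genes under other centring, scaling, filters and probe rules, of which 102 (scaled arrays) to 127 (values as deposited) were among the original 132. It moved to 259 genes (110 higher, 149 lower) without the origin block, 62 (23 and 39) with 1 mean per origin, 69 (25 and 44) with the record block as a term, 48 (16 and 32) with the earlier record block alone, and 198 (82 and 116) with PPC as an origin of its own. The original 132 all passed without the origin block and with PPC as its own origin. Only 49 of them passed with 1 mean per origin, 63 with the record term and 31 with the earlier record block alone. With each probe as its own row and probes without 1 gene symbol included, 536 of 28316 probes (211 higher, 325 lower) passed, 266 of them with 1 symbol. Leaving out 1 line gave 68 (without MDA2A) to 170 (without 22Rv1) genes, 25 to 76 of them higher and 43 to 94 lower, with 77 without PPC, 85 without PC3 and 75 without LNCaP, and 34 higher without MDA2B. Between 55 (without PPC) and 116 (without 22Rv1) of the original 132 passed in these fits. Of the 24 genes named for the class comparison none changed direction in the fits per gene, of which that on genes measured in all 8 lines held 19 of them. These genes were chosen for classes that did not overlap, so leaving out lines or averaging per origin could hardly turn their direction. With the earlier record block alone 12 of the 24 passed, and with 1 mean per origin 14 passed. The mean of the basal list was -1.448 after quantile normalization, -1.418 with scaled arrays, -1.553 with the probe of the largest spread, -1.408 without the origin block and -1.345 with the record term, each short of the threshold, and -1.683 to -1.264 without 1 line, short without LAPC4, DU145, LNCaP or 22Rv1. Its adjusted p ranged from 0.000693 to 0.1368 over all settings.

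Without 1 line, the cholesterol list ranged from 0.2649 to 0.5265 and lost its call without PPC or LAPC4. The leukocyte list (-1.076 to 0.1273) passed without PPC or DU145, and its mean turned above 0 without PC3. The oxidative stress list (-0.9298 to -0.32) passed without PC3, the tumour suppressor list (0.377 to 0.5498) without LAPC4 or DU145, the stromal list (-0.6884 to -0.3401) without DU145 and the nuclear receptor list (0.4793 to 0.6911) without 22Rv1. The melanocyte list's mean, -0.02 with all lines, ranged from -0.116 (without LNCaP, where the camera direction turned from up to down) to 0.5265 (without DU145), so it had no settled sign. The androgen-responsive, luminal, mesenchymal, cell cycle and cancer testis lists kept direction and call under all settings run with the preset correlation, and all 5 calls were lost with an estimated correlation.

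Genes that turned direction were all far from the threshold. With values as deposited NTS was 0.002158. After quantile normalization ISG20 was 0.07837, S100B 0.2755 and MMP13 0.06462, and with scaled arrays 0.04391, 0.1258 and 0.04224. FGB was -0.00904 when measured in at least 2 lines of each class. With 1 mean per origin ISG20 was 0.05046 and NTS 0.1114, and with the earlier record block alone FGB was -0.4416 and MMP13 0.0125. Without 1 line the ranges were -0.6145 to 0.1081 for ADAM9, -0.04721 to 0.8534 for ALDH3A2, -1.509 to 1.026 for BST2, -0.9371 to 0.2649 for CYP1B1, -0.1002 to 0.3859 for FGB, -0.6135 to 0.0232 for GCLC, -0.2233 to 0.1 for ISG20, -0.4138 to 0.04391 for MMP13, -0.5823 to 0.3902 for NTS, -1.216 to 0.1163 for SRXN1, -0.5781 to 1.02 for SYP and -0.2763 to 0.1855 for TTR.

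Genes differing between origins fell from 247 to 18 with scaled arrays. Over the 1000 genes with the largest SD the correlation was 0.8438 for MDA2B and MDA2A and 0.4556 for PPC and PC3. Genes apart between MDA2B and MDA2A were 144 after quantile normalization. With a gap of 1.5 log2 units there were 465 line-specific genes, 74 for same-origin pairs, 680 genes apart between PPC and PC3 and 671 between MDA2B and MDA2A, and with a gap of 3 there were 67, 8, 129 and 56. Signal over background was not used here, so which low ratios are limited by dim spots stays open.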

Other observations

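The tests of zinc finger genes, of windows of genes and of the STAT3 neighbourhood were chosen after results had been seen. Zinc finger genes with ZNF symbols, many of which encode transcriptional repressors, were over-represented among genes higher in the sensitive lines, or lower if the ratio runs the other way. Of 214 such genes 7 rose and 0 fell, against 45 of 8922 other genes that rose (Fisher's exact test p = 0.000192). Their median difference was 0.35 log2 units, 67.3% of them lay above 0 against 45.8% of other genes, and the exact permutation p of their score was 0.0179, the smallest that 56 splits of 8 lines counted as independent can give. The 12 splits that keep lines of 1 origin together could give no p below 0.0833. The direction held under each scaling, with medians of 0.30 to 0.41 and Fisher's exact p from 6.9e-06 (values as deposited) to 0.0129 (quantile normalization). Many of these genes lie in clusters, so they are not independent of each other.

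KLK3, which encodes prostate-specific antigen, had a class difference of 0.10 log2 units. Its 2 probes ran from -0.36 in MDA2A to 1.38 in MDA2B and from 0.17 in DU145 to 1.65 in MDA2B. They read 0.67 and 1.08 in LNCaP against 0.87 and 1.23 in PC3, although LNCaP is known for making the protein. ETV1 stood at 4.74, 3.56 and 0.45 on its 3 probes in MDA2B and at 4.57, 3.16 and -0.37 in MDA2A. No explanation was tested for these values.

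Genes that neighbour each other on a chromosome varied together across the 8 lines, with a median correlation of 0.166 over 8070 neighbouring pairs against at most 0.0228 in 100 shuffled orders. Without neighbours whose symbols share their first 3 letters, a proxy for tandem relatives, it was 0.163 against at most 0.0235. With the class means removed it was 0.168. In windows of 15 neighbouring genes, 11 of the 16 most extreme windows (1 above and 1 below per line) went beyond all shuffles. Window values are mean log2 differences from the median of the other lines, with large differences of single genes capped. This mean was -1.31 in DU145 for the window from SLC7A8 to CHMP4A, with all 15 genes below the median of the other lines. It was 1.31 in PPC from SEC24C to EIF5AL1, and -1.04 in 22Rv1 from SOCS5 to MTIF2. A candidate explanation is gain or loss of chromosome segments, for which copy number was not analysed here.

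The low STAT3 level of PPC and PC3 was shared by some of the genes near it. Of the 8 nearest measured genes, 3 (GHDC, STAT5B and ATP6V0A1) lay at least 1 log2 unit below all other lines in both, where 0.778% of genes do so, and none of 10000 random draws had as many, the most being 2 (one-sided permutation p = 1e-04, the smallest they can give). STAT5B stood at -3.00 in PPC and -3.77 in PC3 against -0.77 to 0.00 elsewhere. The genes directly beside STAT3, STAT5A and CAVIN1, were low in most lines and not below all others in both, and ZNF385C, NAGLU and RETREG3 did not meet the rule either. A loss of 1 chromosome segment, or a gain if the ratio runs the other way, present before PPC and PC3 parted, may underlie these levels. This hypothesis was found and tested on the same values.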
